A study of Mus musculus with 6 samples.

How the data were processed

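Total RNA was taken from laser-microdissected prospective lens tissue of 6 mouse embryos at embryonic day E10.25, 3 wild type and 3 Pax6-/-, on a mixed FVB and 129 background. Per the labels' protocols, 15 ng of RNA per embryo was amplified to cDNA with a Pico whole-transcriptome kit, labelled with biotin and hybridised to 1 bead array per embryo. Amplification from so little RNA adds noise to dim genes, and the arrays read relative abundance, not cell number. All 6 arrays lay on 1 slide, on alternating positions for the genotypes, so no slide effect separates them. Groups and replicate numbers came from the sample titles, and embryos count as independent replicates per the series' design text.

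The deposited non-normalised table holds, per the file headers, the mean bead intensity of each probe on a linear scale with its bead standard error, its number of beads and a detection p-value. The deposited detection p-values come from GenomeStudio, per the submitters' processing notes, and compare a probe with the negative-control beads of its array. A second deposited table holds the authors' processed intensity values. It is linear and reaches below 0 (minimum -16.5 to -19.8), its array medians are 6.89 to 6.91, and each column ranks probes exactly as the raw signal of its own array does (Spearman correlation 1, at most 0.787 with another array). It is therefore background-subtracted and scaled between arrays, by a method and settings not given in the sources used here, and it served only as an alternative. The GenomeStudio version is not given in the sources used here. No column of sample values was left unmapped.

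Probes were named through the platform annotation. Of 46632 probes, 29976 had 1 gene symbol, 10 had several and were left unnamed, and 16646 had none. Symbols were checked by gene identifier against a RefSeq gene table of the mouse assembly GRCm38.p6: 29921 matched, 55 did not and kept the annotation's name, and 0 changed. The array files name no genome build, so that table supplied names, chromosomes and which genes lie near each other, and no coordinates are given.

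Intensities were processed with limma 3.58.1 in R 4.3.3 by its neqc procedure: normexp background correction with the negative-control distribution inferred from the detection p-values, an offset of 16, quantile normalisation between arrays and log2. The offset and the quantile step shrink the changes of dim genes and hide any change in total RNA. Probes were kept at a detection p under 0.05 on at least 3 of the 6 arrays, which left 17751 probes. For each gene the probe with the highest mean over the 6 arrays was used, giving 13805 genes or unnamed probes, 9195 named. Where a gene was not above background on any array of a genotype, only a bound is given ("at least N-fold"), as the mean of the bright genotype over the mean, per dim array, of the higher of the probe's own value and the lowest detected signal. Among 31 named genes with several kept probes, the probes shared a sign in 22 and differed in 9 (Apaf1, Bcl2l11, Ccnd2, Dlk1, Fgfr2, Meis1, Pdgfra, Top2a and Tyms).

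Signal depth was broadly similar between arrays, with some tilt to the wild type. Of the probes, 16876 to 18736 were above background on a wild-type array and 16335 to 17623 on a Pax6-/- array. A median of 37 beads stood behind each value (at least 7). Over the probes above background, the median standard error of the bead mean was 3.51% to 3.74% of the signal. This covers technical error within an array only.

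The comparison was Pax6-/- minus wild type with lmFit and eBayes, without covariates, and Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With 4 residual degrees of freedom and 3 arrays per genotype, no exact permutation test can go below 0.1, so p-values rest on the variance model of limma. The script was tested on simulated data for this comparison, with 200 of the 13805 genes changed in each of 20 runs. It recovered 0.149% of the genes changed by a log2 of 1, 17.9% of those changed by 2 and 69.9% of those changed by 4, with 4.74% false calls among the calls. Of 400 simulated unchanged lists of 20 genes, 0 were called after adjustment, and 20 of 20 shifted lists were found at an unadjusted camera p under 0.05. The simulated genes varied independently of each other, so this says nothing about false calls for lists whose members move together. Changes below 4-fold were thus rarely detectable gene by gene at this size. The simulation called 61.15 genes per run on average, against 12 in the data. The adjusted threshold is stricter where fewer genes pass, so these recoveries can be too high for the data.

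The lists covered lens crystallins and fibre proteins, lens placode regulators, Pax6-linked lens genes, extracellular matrix, surface ectoderm, BMP, FGF and ERK, Wnt, actin and apical constriction, cell cycle, p53 and apoptosis, Notch, retinoic acid, other placodes, optic cup and neuroectoderm, mesenchyme and neural crest, red blood cells, endothelium, macrophages, and immediate early genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists. No list held its call at an adjusted p under 0.05 with an estimated correlation. The estimate was 0.328 for red blood cell, 0.110 for mesenchyme, 0.102 for crystallin, 0.027 for optic cup and 0.018 for surface ectoderm genes. It was below the preset for lens regulators (-0.008), Pax6-linked (-0.042) and Wnt genes (-0.007), so a higher correlation between members is not what raised their p. With an estimated correlation camera uses the residual degrees of freedom, here 4, and with the preset it does not. The preset p-values therefore carry less of the uncertainty of 3 embryos per genotype. Members were also counted by p adjusted over the list alone. In fry, a second set test that asks whether the genes of a set move one way on balance, the adjusted p was 0.0114 for crystallins and fibre proteins, 0.000555 for lens regulators, 0.000244 for Pax6-linked genes, 0.0420 for endothelium (higher) and 0.0478 each for red blood cell, optic cup, surface ectoderm (higher) and FGF and ERK genes (lower). It was 0.113 for mesenchyme and 0.124 for Wnt genes. The mixed form of fry counts changes in either direction, and a few strong members can carry it. Its adjusted p was 0.110 for cell cycle, 0.167 for p53 and apoptosis and 0.880 for macrophage genes. It was under 0.05 for every other list.

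Named genes followed a rule: Pax6, then genes with an established symbol that passed over all genes, were above background on all arrays of the brighter genotype and did not overlap between genotypes, up to 10 per direction by size of change and filled to 5 by unadjusted p, then up to 4 members per list with the smallest adjusted p (10 for the first 3 lens lists). The rule took 96 genes. Those that passed are given with values and most others only as counts. Embryo sex was read from Xist and Y-linked probes. Other backgrounds, normalisations, offsets, filters, probe rules, variance models, the deposited normalised values, the replicate number as a block and leaving out each array were tried as alternatives. Probes without a gene name were tested but not described beyond those that passed.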

Results

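RNA from the prospective lens tissue of single mouse embryos was profiled at embryonic day E10.25 on Illumina bead arrays. The lens placode is the thickened patch of head surface ectoderm that gives rise to the lens, and Pax6 is a paired-box and homeobox transcription factor known to be needed for eye development. Tissue was cut from frozen sections by laser microdissection. Each array carried amplified cDNA from the 2 prospective lens areas of 1 embryo. There were 3 wild-type embryos, in which the lens placode was taken, and 3 Pax6-/- embryos, in which the surface ectoderm was taken. The comparison asks which genes differ in this tissue when Pax6 function is missing. Every array held 46632 probes. Raw median intensities ran from 55.2 to 64.3, and 35.0% to 40.2% of the probes were above background on an array. After the filter on dim probes 13805 genes or unnamed probes were tested, 9195 of them with a gene symbol. Across these genes the arrays correlated at 0.786 to 0.839 within the wild type, at 0.809 to 0.832 within Pax6-/- and at 0.746 to 0.835 between the genotypes. The 3 arrays per genotype limit the precision of every value. Levels below are means ± SD of normalised log2 intensities over 3 arrays, and log2 changes are Pax6-/- minus wild type ± the standard error (SE) of the limma fit.

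Pax6 transcript was still measured in the Pax6-/- tissue, at a lower level. Pax6 lies on chromosome 2, and its 3 probes were above background on all 6 arrays. On the probe used for the gene, the wild-type arrays read 10.52, 10.17 and 10.71 and the Pax6-/- arrays 9.79, 9.93 and 10.11. The log2 changes of the 3 probes in the fit over all probes were -0.53 ± 0.26, -0.83 ± 0.25 and -0.996 ± 0.301. All Pax6-/- arrays were below all wild-type arrays on each probe. None of the 3 passed over all probes, with limma adjusted p of 0.638, 0.376 and 0.380. The allele is not described in the labels, so a probe outside its altered part would check nothing about the genotype.

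Regulators and products of the lens were among the genes with the largest falls in Pax6-/- tissue. Maf, a bZIP transcription factor that drives crystallin expression and fibre cell differentiation, went from 10.68 ± 0.12 in the wild type to a level not above background on any Pax6-/- array. It was at least 43.7-fold lower (adjusted p = 0.0021). Prox1, a homeobox factor of fibre cell elongation, fell from 10.66 ± 0.50 to 5.16 ± 0.23 (adjusted p = 0.021) and was above background on 1 of the 3 Pax6-/- arrays. Crybb3, which encodes a beta-crystallin, fell from 9.49 ± 0.47 to 5.10 ± 0.11 (adjusted p = 0.025). Tnc, the matrix glycoprotein tenascin C, was not above background on any Pax6-/- array and was at least 19.1-fold lower (adjusted p = 0.045). Tgm2, a protein-crosslinking transglutaminase, fell from 9.20 ± 0.24 to 5.00 ± 0.34 (adjusted p = 0.025). Islr2, a membrane protein with immunoglobulin and leucine-rich repeats, fell from 7.999 ± 0.117 to 5.25 ± 0.18 (adjusted p = 0.045). Crybb3 and Tgm2 were above background on 1 of the 3 Pax6-/- arrays and Islr2 on 2, so their levels there are partly background. A second, dimmer probe changed by -0.76 for Tnc and by -0.35 for Crybb3.

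Only 2 named genes rose past the threshold in the Pax6-/- tissue. Rnf144b, which encodes a RING-type ubiquitin ligase, was not above background on any wild-type array and was at least 10.9-fold higher in Pax6-/- (8.61 ± 0.55, adjusted p = 0.045). Slc38a8, an amino acid transporter of the SLC38 family, rose 11.8-fold, from 5.85 ± 0.50 to 9.41 ± 0.21 (adjusted p = 0.049). The next 3 by unadjusted p missed the threshold, each with an adjusted p of 0.063. They were the forkhead gene Foxd1 (log2 change 3.11 ± 0.33), the interferon-induced membrane protein gene Ifitm3 (2.07 ± 0.22) and Mab21l4, which was not above background on any wild-type array (at least 6.24-fold higher). Foxd1 was above background on 1 and Ifitm3 on 2 of the 3 wild-type arrays.

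**Figure D1:**
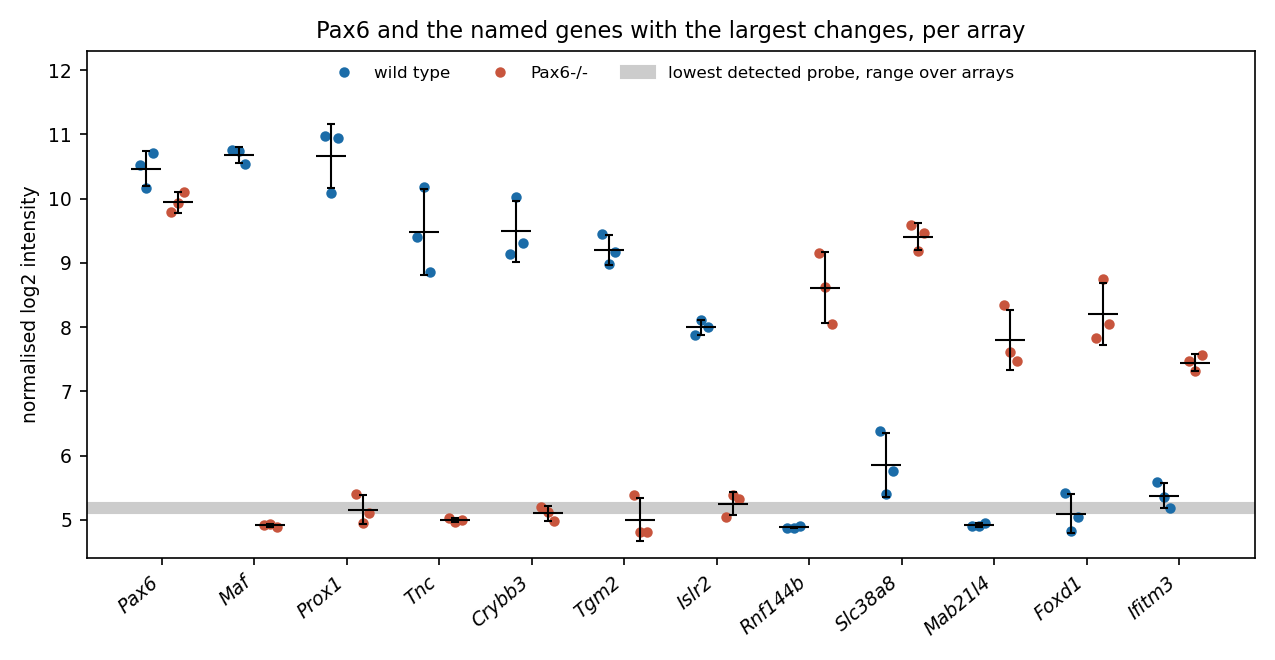
Normalised log2 intensity (vertical axis) of Pax6 and of the named genes with the largest falls and rises, with a point per array, a bar at the mean and whiskers of 1 SD for 3 wild-type and 3 Pax6-/- arrays. The grey band spans the lowest signal of a detected probe on the 6 arrays; Maf lies at 10.68 in the wild type and below the band in Pax6-/-, and Rnf144b lies below the band in the wild type and at 8.61 in Pax6-/-.

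In all, 12 of the 13805 genes or probes passed an adjusted p of 0.05 in limma, 8 lower and 4 higher in Pax6-/-. In each of the 12 the 3 arrays of a genotype did not overlap those of the other. Of the 12, 4 were probes without a gene name, chosen here only because they passed: ILMN_2472094 and ILMN_2437422 were lower (at least 6.86-fold and 4.37-fold), and ILMN_1252744 and ILMN_1243664 were higher (at least 9.31-fold and 4.86-fold), each not above background on any array of the dimmer genotype. At an unadjusted p of 0.05 there were 1241 genes, 652 lower and 589 higher, against 690.25 given by chance. The genotypes did not overlap in 15.3% of all genes, where chance gives 10%. Counts depended on single arrays: 0 genes passed without wild-type array 1 or 2, and 1 gene passed without wild-type array 3 or any single Pax6-/- array. The split of 8 lower and 4 higher became 7 and 0 with arrays scaled to a common median and 10 and 1 with cyclic loess.

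Crystallins and fibre cell proteins were lower in Pax6-/- as a group. The list has 26 genes. Of these, 24 were on the array, and 15 of the 24 did not pass the detection filter, so most of the list was not measured. Cryba2, Crygs and Lim2, for example, were not above background on any array of a genotype. All 9 measured members had a negative change, with a median of -1.94, and 8 of them were above background on all 3 wild-type arrays. Camera, a competitive test against all other genes, placed the list lower (adjusted p = 1.03e-07). With an estimated correlation between genes its adjusted p = 0.077. Crybb3 passed over all genes, and 4 members fell at p adjusted over the list alone: Crybb3, the gamma-crystallin genes Cryge (-3.67 ± 0.52) and Crygc (at least 2.93-fold lower), and Mip, the main water channel of fibre cells (-2.90 ± 0.72). The other 5 did not pass, among them Cryab at -1.94 ± 0.88 and Cryba1 at -2.13 ± 1.21. Of the 3 Pax6-/- arrays, Cryge and Cryba1 were above background on 1 and Mip and Cryab on 2, and Cryba1 was on 2 wild-type arrays. Cryaa was not tested because it was above background on 2 wild-type arrays and no Pax6-/- array. Red blood cell and optic cup marker lists were higher in the same Pax6-/- arrays, with the values given further on.

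Among 16 measured regulators of the lens placode, 7 fell and 1 rose at p adjusted over the list alone, and Maf and Prox1 passed over all genes. The other 5 that fell were Tdrd7, an RNA granule protein gene of the lens (-2.59 ± 0.53, above background on 1 Pax6-/- array), the SoxB1 factor Sox2 (-2.15 ± 0.40), Mab21l1 (-1.75 ± 0.27), the homeobox genes Six3 (-1.22 ± 0.32) and Pitx3, which was not above background in Pax6-/- and at least 2.35-fold lower. A second, dimmer probe of Sox2 changed by -0.40 ± 0.55. Meis1 rose on the probe used (1.35 ± 0.37), while its 3 other probes had negative changes. Foxe3, a forkhead factor of the lens vesicle, was dim in the wild type, at 5.60 ± 0.10, and not above background on any Pax6-/- array. It was at least 1.29-fold lower and did not pass (limma adjusted p = 0.088 over the list alone). Meis2 stood at 10.17 ± 0.24 and 10.79 ± 0.09 and did not pass. The list was lower as a whole (median -0.51, camera adjusted p = 1.6e-05), and with an estimated correlation its adjusted p = 0.072. Pax6, the targeted gene, is itself among the 16, at -0.53 without passing, and counts toward these list values.

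A list of 12 measured genes that earlier lens studies linked to Pax6 had 7 members that fell and 1 that rose at p adjusted over the list alone, with 2, Maf and Prox1, passing over all genes. Of the 12, 11 also stand in another list, and the literature behind the list can include work on this tissue, so its direction is not independent evidence. Beyond the regulators above, Sfrp2, a secreted Wnt antagonist, fell by 1.42 ± 0.28 from a high wild-type level of 12.59 ± 0.13. The cation channel gene Trpm3 fell by 1.29 ± 0.33. Dkk1, another Wnt antagonist above background on 2 wild-type arrays, rose by 1.28 ± 0.41. The median change was -1.25, or -1.22 with undetected genes set at their bounds. Camera gave an adjusted p = 4.22e-09, and with an estimated correlation the adjusted p = 0.052.

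**Figure D2:**
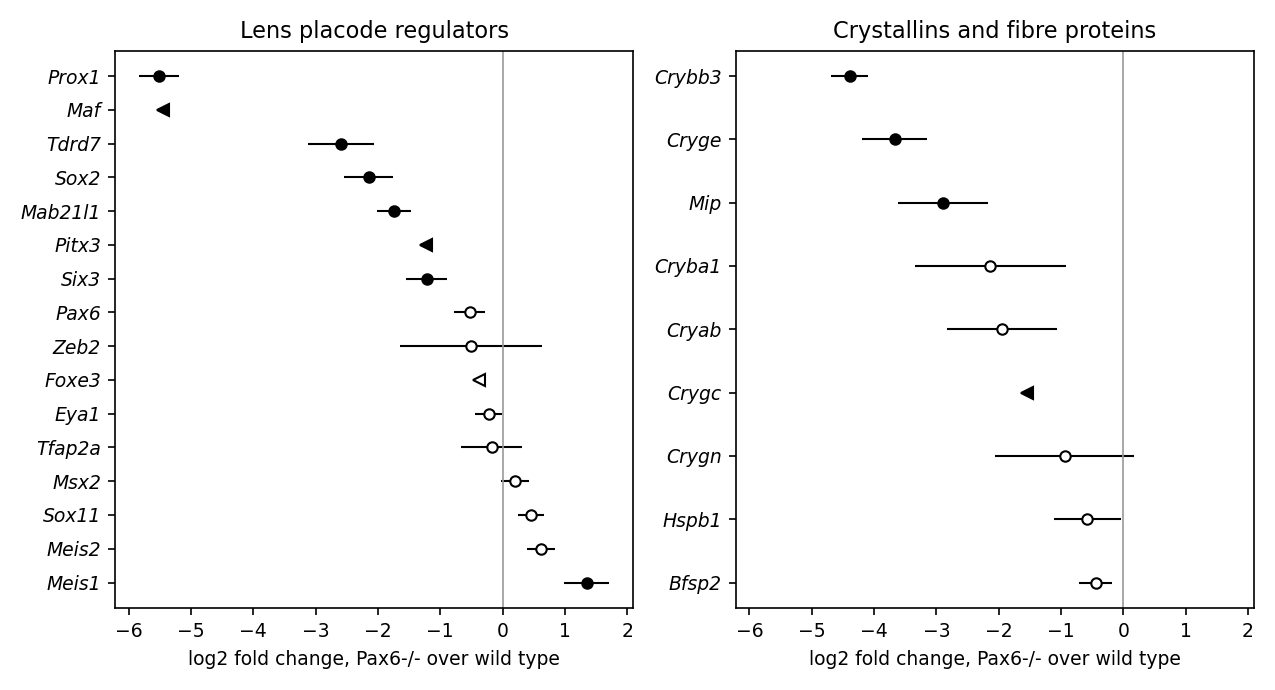
Log2 fold change, Pax6-/- over wild type (horizontal axis, with the limma SE as whiskers), of the measured members of the lens placode regulator list (left) and of the crystallin and fibre protein list (right), from 3 arrays per genotype. Filled symbols passed at p adjusted over the list alone and open symbols did not. Triangles mark genes not above background in Pax6-/-, drawn at their bound without whiskers. All 9 crystallin and fibre genes lie below 0, and 12 of the 16 regulators, Pax6 among them, do.

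Matrix and adhesion genes did not move in a single direction as a group. Of 32 measured genes of the extracellular matrix, basement membrane and matrix receptors, 3 fell and 1 rose at p adjusted over the list alone, with Tnc passing over all genes. Besides Tnc, Has2, which makes hyaluronan, fell by 2.74 ± 0.26 from 9.49 ± 0.32, and the integrin gene Itgav was not above background in Pax6-/- (at least 2.32-fold lower). Col9a1, a collagen IX chain, rose by 2.62 ± 0.63. The list as a whole did not pass (camera adjusted p = 0.26). Of 25 measured genes of the actin cytoskeleton and apical constriction, Cdh2, encoding N-cadherin, was the 1 that passed over the list alone. It fell by 3.07 ± 0.41, from 8.43 ± 0.74 to 5.35 ± 0.19 with 2 Pax6-/- arrays above background (limma adjusted p = 0.0077 over the list alone), and 2 further probes of Cdh2 changed by -2.71 and -1.07. That list did not pass in a single direction (camera adjusted p = 0.52), and none of its members passed over all genes. Its mixed fry adjusted p was 0.0086.

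Signalling lists gave a few single changes, and none of their members passed over all genes. At an unadjusted limma p of 0.05, 3 Wnt genes were higher and 4 lower, and 3 retinoic acid genes higher and 2 lower. The counts were 2 and 2 for FGF and ERK, 2 and 0 for BMP and 1 and 1 for Notch genes. Mixed fry had adjusted p of 0.000404 for Wnt and 0.000653 each for retinoic acid and for FGF and ERK genes. It had 0.016 for BMP and 0.017 for Notch genes. Of 12 BMP pathway genes, the ligand gene Bmp4 (3.27 ± 0.69) and the receptor gene Bmpr2 (1.15 ± 0.27) rose at p adjusted over the list alone, while the list did not pass (camera adjusted p = 0.52). Of 14 FGF and ERK response genes, the ETS factor gene Etv1 fell by 2.78 ± 0.46, and Etv5 stood at -3.02 ± 0.95 without passing. A second, dimmer probe changed by -0.39 ± 0.87 for Etv1 and by -2.39 ± 0.41 for Etv5. That list had a camera adjusted p = 0.18, and fry, a second set test, placed it lower (adjusted p = 0.0478). Of 21 Wnt pathway genes, Sfrp2 and the transcription factor gene Tcf7l2 (-2.48 ± 0.56) fell, and the list was lower (camera adjusted p = 0.044, with an estimated correlation adjusted p = 0.21). Dimmer probes of Tcf7l2 changed by -0.79 and -0.63. Sfrp2 restrains and Tcf7l2 carries canonical Wnt signalling. The camera adjusted p of the Wnt list was 0.063, 0.16 and 0.069 without wild-type array 1, 2 or 3, and 0.10 and 0.34 without Pax6-/- array 2 or 3. Of 9 retinoic acid genes, the synthesis enzyme gene Aldh1a3 fell, from 10.14 ± 0.05 to 8.13 ± 0.40, and Crabp2, a retinoid binding protein, and the receptor gene Rxrb rose by 1.02 ± 0.25 and 1.48 ± 0.43 (camera adjusted p = 0.52 for the list). A second Aldh1a3 probe, at 10.03 in the wild type, changed by -4.01 ± 0.47, so the size of its fall depends on the probe. Of 12 Notch pathway genes, Dlk1 rose (3.99 ± 0.63) on 1 probe and had -0.59 on its other probe (camera adjusted p = 0.52). Bmp4 was above background on 2 and Dlk1 on 1 of the 3 wild-type arrays, and Etv5 on 2 of the 3 Pax6-/- arrays.

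Proliferation and death genes showed no passing change. None of 25 cell cycle genes or 15 genes of the p53 response and apoptosis passed in limma, over all genes or over the list alone, against 2 and 1 at an unadjusted p of 0.05. Examples were Rrm2 (10.21 ± 0.06 in the wild type and 10.58 ± 0.13 in Pax6-/-) and Bcl2l11, at -0.98 ± 0.26 with probes that differed in sign. The lists had camera adjusted p of 0.17 and 0.32. Of 7 immediate early and heat shock genes, which can mark tissue handling, Zfp36 fell by 1.16 ± 0.24 over the list alone, and the list did not pass (camera adjusted p = 0.24).

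Surface ectoderm genes were higher in Pax6-/- as a list, by a small margin. Of 23 measured epithelial and early epidermal genes, none passed over all genes. At p adjusted over the list alone 3 rose and none fell. These were the desmosomal plakophilin gene Pkp3 (7.16 ± 0.28 to 9.36 ± 0.30), the AP-2 factor gene Tfap2b (9.73 ± 0.26 to 11.35 ± 0.10) and the grainyhead factor gene Grhl3, which was not above background in the wild type (at least 3.07-fold higher). Epcam had a change of -0.80 ± 0.21 that did not pass (limma adjusted p = 0.051 over the list alone). The median of the list was 0.28 and its camera adjusted p = 0.044. With an estimated correlation the adjusted p = 0.24. The camera adjusted p of this list was 0.17 and 0.15 without wild-type array 2 or 3, and 0.33 and 0.16 without Pax6-/- array 1 or 2. Of 8 measured genes of other cranial placodes, none passed over all genes. At p adjusted over the list alone Otx1 fell by 2.67 ± 0.46 and Dlx5 rose by 1.01 ± 0.26. The list did not pass (camera adjusted p = 0.69).

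Markers of other tissues were also higher in the Pax6-/- arrays. No member of these lists passed over all genes, and the genes said to rise or fall did so at p adjusted over the list alone. All 7 measured red blood cell genes had positive changes, and the list means of the arrays were 5.78 to 7.41 in the wild type and 8.13 to 8.76 in Pax6-/- (camera adjusted p = 0.00011, with an estimated correlation adjusted p = 0.21). The anion exchanger gene Slc4a1 (2.72 ± 0.46), the carbonic anhydrase gene Car2 (1.22 ± 0.36) and the embryonic globin gene Hba-x (2.63 ± 0.82) rose over the list alone. Of 12 optic cup and neuroectoderm genes, Otx2 (2.11 ± 0.57), Rax (1.86 ± 0.50) and Zic1 (2.52 ± 0.70) rose, and the list was higher (camera adjusted p = 0.0051, with an estimated correlation adjusted p = 0.20). Without wild-type array 3 the camera adjusted p of the optic cup list was 0.084. Of 14 mesenchyme and neural crest genes, Twist2 (at least 2.89-fold higher), the collagen gene Col5a1 (1.46 ± 0.33) and Prrx2 (2.09 ± 0.56) rose. Pdgfra fell by 3.82 ± 0.70 on the probe used, with 2 Pax6-/- arrays above background, and had 0.11 on its other probe. The mesenchyme list was higher (camera adjusted p = 0.023, with an estimated correlation adjusted p = 0.28), and its camera adjusted p without wild-type array 1 was 0.13, without Pax6-/- array 1 it was 0.27 and without Pax6-/- array 2 it was 0.30. Of 10 endothelial genes, the tight junction gene Cldn5 rose by 2.21 ± 0.37, and the list did not pass in camera (adjusted p = 0.087, or 0.043 without Pax6-/- array 3) and was higher in fry (adjusted p = 0.0420). Of the 3 wild-type arrays, Slc4a1 and Rax were above background on 1 and Otx2 and Cldn5 on 2. None of 5 macrophage genes passed over all genes or over the list alone in limma, against 0 at an unadjusted p of 0.05. The macrophage list had a camera adjusted p = 0.69 with a median of -0.23, a mean of 0.03 and a lower direction in the test.

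**Figure D3:**
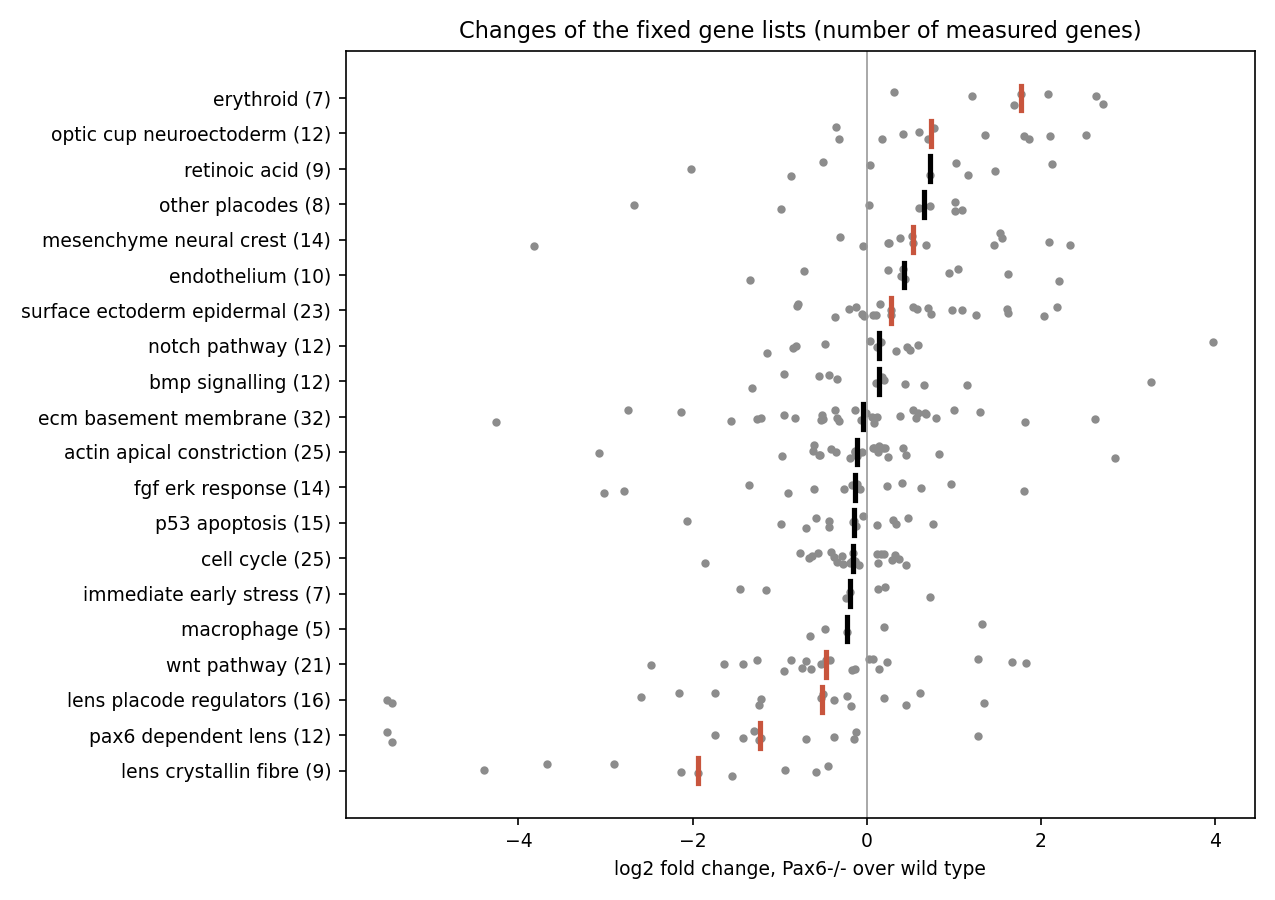
Log2 fold changes, Pax6-/- over wild type (horizontal axis), of the measured members of 20 gene lists (vertical axis, number of genes in brackets), with a grey point per gene from 3 arrays per genotype and a bar at the list median. Genes not above background in a genotype are drawn at their bound. Red bars mark the 8 lists with a camera adjusted p under 0.05 at a preset correlation; medians run from -1.94 for crystallins and fibre proteins to 1.77 for red blood cell genes.

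None of 179 genes within 20 Mb of Pax6 on chromosome 2 passed in limma, against 8 of 9006 other genes (two-sided Fisher exact p = 1). With so few calls this test has little power, and counts at an unadjusted p under 0.05 were added, not having been planned. They gave 16 of the 179 genes (8.94%) and 868 of the others (9.64%, Fisher exact p = 0.898). The test bears on strain sequence that could travel with the allele on the mixed FVB and 129 background. With a window of 5 Mb the share at an unadjusted p under 0.05 was 7 of 30 genes (23.3%) and the Fisher exact p = 0.021, or 0.064 after Benjamini-Hochberg adjustment over the 3 windows tried.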

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

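A single result stood out in data outside the main comparison, and its test on the lens genes was chosen after those genes had been seen. Y-linked probes were above background on Pax6-/- array 1 and on no other array: 4 of 7 probes of Eif2s3y, Kdm5d and Uty, against 0 of 7 on each of the other 5 arrays. On the same array the brighter Xist probe read 5.72, while it read 10.07 to 10.64 on the other 5. By these genes, which follow the sex chromosomes, the embryo behind Pax6-/- array 1 was male and the other 5 were female. Of the 8 named genes past the threshold, 0 lie on X or Y, and the 4 unnamed probes have no chromosome here. Embryo sex as the source of the lower lens genes was tested by leaving out that array. The median log2 change of the 11 crystallins and regulators that had passed over their lists alone was -2.59 with all arrays and -2.295 between the female embryos only, and for all 25 measured crystallins and regulators it was -1.22 and -1.09. This argues against embryo sex as the source of the fall. The 2 estimates share the wild-type arrays and the Pax6-/- arrays other than array 1, so they are not independent. Without the male array 1 gene passed over all genes, against 12 with it, and a fit on fewer arrays loses genes whichever array is left out.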

How the results depend on the processing

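The alternatives were fixed before the data were examined, except 2 that were chosen after seeing the data: leaving out each array with the filter of all 6 arrays, and counting genes near Pax6 at an unadjusted p. No setting gave any of the 8 named genes past the threshold the opposite sign, but the counts moved widely. Of 12 genes (8 lower, 4 higher), 2 (2 and 0) passed with no background correction, 4 (4 and 0) with normexp without negative controls, 7 (7 and 0) with arrays scaled to a common median, 11 (10 and 1) with cyclic loess, 14 (10 and 4) with an offset of 1, 6 (5 and 1) with an offset of 50 and 6 (4 and 2) with the deposited normalised values. Common-median scaling moved the median change of all genes from 0.07 to -0.20, so changes there are relative to that shift. Without a detection filter 3 passed (2 and 1) among 34367 tested. With detection p under 0.01 on all arrays of a genotype 47 passed (30 and 17) among 7428, including all 12. This stricter filter uses the genotype labels, so it is not independent of the comparison. At an unadjusted limma p of 0.05 it gave 1004 of 7428, against 1241 of 13805 with the main filter, which ignores genotype. With every probe tested 4 passed (4 and 0), with the mean of a gene's probes 10 (6 and 4), with array weights 8 (7 and 1) and with a trended, robust variance 3 (3 and 0). A separate unequal-variance test per gene gave 0 (0 and 0), with 779 at an unadjusted p of 0.05. Leaving out 1 array gave 0 to 1 genes (0 to 1 lower, 0 to 1 higher), where the filter also removes some genes found in a single genotype, and 0 to 2 with the filter of all 6 arrays (0 to 2 lower, 0 to 1 higher). Without wild-type array 3, the 1 gene that passed was not among the 12. Other than through the number of genes tested or arrays used, the cause was not tested. Maf kept its call in 21 of 24 alternatives that tested it and Tnc and Rnf144b in 4 of 24. Of 27 alternatives, Prox1 kept its call in 13, Crybb3 and Tgm2 in 9, Islr2 in 8 and Slc38a8 in 3. The change of Pax6 ran from -0.83 to -0.40.

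The replicate numbers do not pair the embryos. Same-numbered arrays had deviations that correlated at 0.005, 0.002 and -0.018, and 1 of 6 arrays correlated best with its own number. With the replicate block 0 genes passed (0 lower, 0 higher), with 1190 at an unadjusted p of 0.05, and the camera adjusted p was 0.052 for the Wnt list and 0.048 for the endothelial list.

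Camera kept the lower call of crystallins, lens regulators and Pax6-linked genes and the higher call of red blood cell genes in 26 of 27 alternatives each, all but the estimated correlation (0.0769, 0.0718, 0.0517 and 0.214). It kept the optic cup call in 24, mesenchyme in 19, surface ectoderm in 14 and Wnt in 11. With the estimated correlation these had adjusted p of 0.202, 0.277, 0.244 and 0.214. Surface ectoderm had 0.0634 with common-median scaling, 0.0660 with an offset of 50, 0.178 with the stricter filter and 0.0538 with the trended variance. Wnt had 0.0647 with common-median scaling, 0.0636 with an offset of 1, 0.113 with no filter and 0.0516 with probe means, and mesenchyme 0.266 with the stricter filter. Endothelium passed with cyclic loess (0.0480), no filter (0.0132) and probe means (0.0489), immediate early genes with no filter (0.0405), and FGF and ERK genes with every probe (0.0406). Leaving out 1 array, with both filters, gave 0.0112 to 0.334 for surface ectoderm, 0.0136 to 0.340 for Wnt, 0.00205 to 0.0839 for optic cup, 0.00367 to 0.301 for mesenchyme and 0.0360 to 0.349 for endothelium. Members passing over the list alone ran from 2 to 4 for crystallins, 5 to 12 for regulators, 0 to 4 for optic cup and 0 to 3 for red blood cell genes. Of genes near Pax6, 0 passed in limma in the windows of 5, 20 and 50 Mb (Fisher exact p = 1 each). Of genes within 5 Mb, 23.3% had an unadjusted p under 0.05 against 9.58% of others (Fisher exact p = 0.0212, or 0.064 adjusted over the 3 windows, which does not pass), while the 20 Mb window showed no difference that passed (8.94% against 9.64%, p = 0.898). Signal near background limits the dim genes, whose changes the offset shrinks.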

Other observations

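Chosen after the results they bear on had been seen were the tests on ectoderm share, the counts of rising markers and their array means, the counts near Pax6 at an unadjusted p with the comparison of distances, and the splits for probes seen in a single genotype. The gene lists, the windows around Pax6 and the splits for genes and lists were planned. The genes named in this paragraph and the next were also chosen after their values were seen, and none of them passed over all genes in the main setting. With the stricter detection filter 47 genes or probes passed, 36 of them named, and 8 of them stand in a fixed list. That filter keeps probes seen on all arrays of a genotype, so it uses the genotype labels and its calls are not independent support. Antxr1, an anthrax toxin receptor that binds matrix, had a log2 change of -3.44 ± 0.36 (from 9.36 ± 0.21), and Fat4, a giant protocadherin, -2.57 ± 0.29 (from 8.48 ± 0.36). Edn1, which encodes the secreted peptide endothelin 1, had -3.61 ± 0.49 and was above background on 1 of 3 Pax6-/- arrays. Anxa1, a phospholipid-binding annexin, had -3.16 ± 0.34 and was also above background on 1 of 3. The doublesex-related factor gene Dmrta2 went from 10.75 ± 0.17 to 8.25 ± 0.54. Their adjusted p in the main limma setting were 0.063 (Antxr1), 0.064 (Fat4), 0.105 (Edn1), 0.063 (Anxa1) and 0.103 (Dmrta2).

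Some genes were seen in a single genotype. Genes or unnamed probes above background on all 3 arrays of 1 genotype and none of the other numbered 270, with 179 seen in the wild type and 91 in Pax6-/-. Of the 10 splits of the 6 arrays, the real 1 gave the most, and the highest other gave 189. The tilt of 179 against 91 cannot be assigned to genotype, because arrays differed in how many probes they detected. A mixed split, wild-type arrays 1 and 2 with Pax6-/- array 1 against the rest, gave 133 against 34. Genes seen only in wild-type arrays included Prokr1, a G protein-coupled receptor gene (at least 7.42-fold lower in Pax6-/-), the fatty acid elongase gene Elovl3 (at least 7.18-fold) and the chemokine gene Cx3cl1 (at least 8.20-fold). Genes seen only in Pax6-/- arrays included the forkhead gene Foxi2 (at least 5.33-fold higher), the matrix metalloproteinase gene Mmp2 (at least 2.39-fold) and the cadherin gene Cdh11 (at least 4.56-fold). Their limma adjusted p were 0.064, 0.064, 0.070, 0.070, 0.142 and 0.191 in that order. For the counts of genes past the threshold and of lists, the real split gave 12 genes and 8 lists, and the highest of the other splits gave 1 gene and 2 lists. With 10 splits no share can go under 0.05, for any of these 3 counts.

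Lens genes were lower in Pax6-/-, and a smaller share of ectoderm in the Pax6-/- dissections was tested as a technical source. With undetected genes at their bounds, all 25 measured crystallins and regulators, Pax6 among them, had a median of -1.22 (95% bootstrap interval -2.13 to -0.45). The 11 that had passed over their lists and fell, chosen for their fall, had -2.59. Each interval resampled the genes of a set, not the embryos, so it leaves out the spread between embryos and treats genes that move together as separate. A loss of ectoderm would lower genes expressed across the surface ectoderm by as much, yet the median of all 23 was 0.28 (0.077 to 0.977) and that of the 12 brighter in the wild type 0.06 (-0.28 to 0.86). Over the genes of these lists, this argues against a smaller ectoderm share as the whole source of the fall, but not as a part of it. It does not do so for the 16 regulators alone (-0.51, -1.75 to -0.15), whose interval overlaps that of the 12. Among bright ectoderm genes, named here after their values were seen, Epcam had -0.80 ± 0.21, Tfap2c -0.79 ± 0.34, Krt18 -0.36 ± 0.27, Cdh1 -0.20 ± 0.23 and Tfap2b 1.62 ± 0.24. Epcam was the lowest of the 23. The list also holds early epidermal genes, and rises among them could offset a loss in its median. Lower expression in the cells themselves and another position of the dissection within the ectoderm both stay open and were not tested, as the labels name lens placode for the wild type and surface ectoderm for Pax6-/-.

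Markers of other tissues were higher in Pax6-/-, and more of each tissue in the dissections may be the source. For red blood cells, 7 of 7 measured genes had positive changes and the array means separated, with Hbb-bh1 at 9.21 ± 2.06 in the wild type and 11.30 ± 0.34 in Pax6-/- and Hba-a1 at 8.42 ± 1.22 and 10.12 ± 0.43, which is consistent with more blood in the Pax6-/- samples. For optic cup and neuroectoderm 10 of 12 genes were positive and the array means separated (5.86 to 6.06 against 6.68 to 7.29), but Mitf and Nes were negative, and more neural tissue cannot be told apart from ectoderm that expresses Otx2, Rax or Zic1 itself. For mesenchyme 11 of 14 genes were positive with overlapping array means (6.52 to 7.16 against 6.86 to 7.68), so this too cannot be told apart from a change in the ectoderm. Of the measured optic cup genes, 1 (Fgf15) also stands in another list, as does Hes5, which was not above background, and 0 genes of the other 2 lists do. Above background on all 3 wild-type arrays were 5 of 7 red blood cell, 6 of 12 optic cup and 8 of 14 mesenchyme genes, and these arrays cannot show which cells express them.

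Genes close to Pax6 had unadjusted p under 0.05 more often than others in the smallest window, an excess that did not pass after adjustment over the windows, and strain sequence carried along with the allele is a candidate explanation. Within 5 Mb, 7 of 30 genes (23.3%) had an unadjusted p under 0.05, against 9.58% of the others (Fisher exact p = 0.0212, or 0.064 adjusted over the 3 windows tried). Of these, Fjx1 (-2.13, above background on 2 Pax6-/- arrays), Rcn1, Trim44, Eif3m and Lgr4 were lower, as was Mettl15, not above background in Pax6-/- (at least 2.24-fold). Abtb2, not above background in the wild type, was at least 1.71-fold higher. Between 5 and 20 Mb the share was 9 of 149 (6.04%), and over the whole 20 Mb window the Fisher exact p was 0.898. Whether the 5 Mb excess comes from flanking sequence, from the missing Pax6 or from chance cannot be told apart with 30 genes and no genotype of the flanks.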
